A study of Chlamydomonas reinhardtii with 28 samples.

How the data were processed

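Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 4 histone marks in vegetative cells of the green alga Chlamydomonas reinhardtii. Per the labels' protocols, cells were grown in TAP medium, fixed with formaldehyde and sonicated, and the chromatin was precipitated with antibodies against H3K4me1, H3K9me1 and H3K4me3 (Abcam) or H3K9me3 (Cell Signaling Technology). The series holds 28 samples, of which 18 are ChIP libraries with a peak list and 10 are input libraries, whose own files were not analysed here. There are 2 strains, CC-5155 of mating type plus (mt+) and CC-5325 of mating type minus (mt−), and 3 genotypes: wild type (WT), a knockout of the DNA methyltransferase gene DNMT1 (dnmt1) and a knockout of SET3 (set3), the last profiled for H3K9me1 alone. Each combination of mark, genotype and strain is represented by 1 library. Per the labels, the H3K4me1, H3K4me3 and H3K9me3 libraries of a strain and genotype share 1 input.

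Each deposited file is a list of narrow peaks called by the authors on a single library. Trim Galore 0.6.7, Bowtie2 2.4.2, Picard, MACS2 2.2.7.1 and deepTools 3.5.1 are named in the submitters' processing notes, without their settings. The genome build is not given in the sources used here. The files name 17 chromosomes, 40 contigs numbered 18 to 57, and a sequence called mating_type_plus, and the peaks span 114 Mb when each sequence is taken to end at its farthest peak. All coordinates are those of the deposited files, counted from 1. For every peak the authors deposited an integer score used for display, a fold enrichment over the local background as a linear ratio, the −log10 p-value and −log10 q-value, and the position of the summit. The lowest −log10 q-value in each deposited list was just above 2, which corresponds to a q-value threshold of 0.01. The fold and q-values are the authors' and were used only to describe, rank or filter peaks within a list, and to recover the depth of each peak call.

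No count of reads is given in the peak lists. The depth behind each call was therefore recovered from the deposited values, because MACS2 computes the fold at a summit as (pileup + 1) / (background + 1) and the p-value from a Poisson distribution with that background. A scale for the ChIP pileup was searched for in each list so that every pileup was a whole number of fragments times the scale. The deposited −log10 p-value was then met within 0.002 for 99.9% to 100% of the summits of every list. The background pileup at the bottom of each list (its 1st percentile) is called the working background below. It is a pileup after scaling and ranged from 15.3 to 34.2. Divided by the ChIP scale, it ranged from 18.9 to 57.6 fragments and was highest for H3K4me3 in WT mt−. The recovery was tested on simulated data: over 4 simulated lists of 3000 summits the largest relative error of the background was 0.00159%. The simulated summits followed the same formula, so they test the search for the scale and not the formula itself. In 1 trial with a wrong scale, on the first part of the WT mt+ H3K4me1 list, only 1.8% of the summits were solved. The overlap functions were tested on 6 simulated lists derived from the WT mt+ H3K9me1 and H3K4me3 lists, and the known kept share was recovered within 3.13 percentage points.

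A WT peak is called kept when at least 1 bp of it is overlapped by a peak of the mutant list of the same strain and mark, and lost otherwise. A mutant peak without an overlapping WT peak is called gained. These words describe peak lists, since a peak can be missing because its signal lies just below the threshold. Shares are given with Wilson 95% confidence intervals, which cover counting error only. The overlap given by chance was obtained from 1000 circular shifts of the second list within each sequence. With 1 library per combination there is no replicate error, and no p-value between genotypes or strains was computed. The mt+ and mt− strains are given side by side instead. Log2 ratios of length and number of peaks were also fitted with strain and genotype as additive terms, chosen after the data were examined, and are given with 95% intervals. The error of that fit is the disagreement between the strains, which stand in for replicates. Fisher's exact test (two-sided) was used for 2 kinds of question within a pair of libraries: whether gained or lost peaks overlap the WT H3K9me1 peaks of the same strain more often than kept peaks (12 tests), and whether WT peaks of a region were lost more or less often than elsewhere (20 tests). Its p-values were adjusted by the Benjamini-Hochberg method within each family. They compare 2 libraries, not the conditions, and they treat neighbouring peaks as independent. Intervals for ratios of kept shares between chromosome ends and interiors came from 1000 resamplings of whole ends and whole interiors.

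A chromosome end was the outermost 50 kb of a chromosome, and a wide peak was one of at least 5 kb. H3K9me1 intervals were formed by joining the peaks of both WT lists over gaps of up to 5 kb, or 2 kb on mating_type_plus, and in the sex-determining region those of at least 5 kb, or 2 kb on mating_type_plus, are given. Those of at least 20 kb that lay outside the chromosome ends and held peaks of both WT strains are called wide intervals. These definitions, the mating_type_plus sequence and the choice of the 12 widest intervals were made after the data were examined. The tests of gained or lost peaks at WT H3K9me1 peaks, and of WT peaks on mating_type_plus, were not in the plan made beforehand. The comparisons of each mutant with WT, of the strains and of the marks were in that plan. So were the test within the sex-determining region and the choice of that region. That region was to be bounded by named mating-type genes or, without names on the build used, to be the first 1 Mb of chromosome 6, and the latter applied. For the region, the covered length was ranked among 1 Mb windows placed every 100 kb on the chromosomes.

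The gene table at hand belongs to assembly 5.5 and lists 17742 genes, 0 of them with a symbol other than the locus tag. Its last gene on chromosome 15 ends at 1.92 Mb, whereas the peaks reach 5.87 Mb there, so the builds differ and none of its coordinates were used. Peaks by gene feature, genes with a peak, the gene lists fixed beforehand and the naming of genes were for this reason not carried out. The rule for named genes was applied to peaks instead: for each mark and mutant, peaks present in both WT lists and overlapping neither mutant list, and the reverse, were ordered by the mean percentile of the authors' fold within the 2 lists that hold them, and the first 12 in each direction were taken.

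Alternatives set before the data were examined were an overlap of at least 50% of the shorter peak, a −log10 q of at least 5, lists of equal length, stricter peaks looked up among all peaks of the other list, and a region widened by 100 kb. Alternatives added later were shares of base pairs instead of peaks, end windows of 100 kb, stricter H3K9me1 lengths, gained peaks counted against both WT strains or against joined H3K9me1 intervals, and the chromosome 6 region without its widest H3K9me1 interval. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.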

Results

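Peak lists of 4 histone marks were compared between WT, dnmt1 and set3 cells of an mt+ and an mt− strain of Chlamydomonas reinhardtii, a haploid alga whose mating type is set by a non-recombining region of chromosome 6. DNMT1 is a maintenance cytosine methyltransferase, and SET3 is a SET-domain protein that monomethylates lysine 9 of histone H3. The series title places the work in the context of DNA methylation and recombination at the sex-determining region. H3K4me1, H3K9me1, H3K4me3 and H3K9me3 were profiled in WT and dnmt1, and H3K9me1 also in set3. There was 1 library per combination, so every comparison below is made within a strain and shown for both strains, without a replicate error. The working background of the peak calls, a scaled pileup, was 15.3 to 16.5 for H3K4me3, 20.03 to 25.9 for H3K9me3, 20.4 to 27.7 for H3K4me1 and 18.9 to 34.2 for H3K9me1.

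In WT cells H3K9me1 formed the widest peaks of the 4 marks. The list held 3831 peaks covering 7.51 Mb in mt+ and 4113 peaks covering 7.91 Mb in mt−, or 6.58% and 6.93% of the sequence. Of these peaks, 282 in mt+ and 308 in mt− were at least 5 kb wide, together 3.70 and 3.87 Mb. The widest peak was 115 kb in mt+ and 98.1 kb in mt−. By contrast, the widest H3K4me3 peak of WT cells was 3.97 kb in mt+ and 6.54 kb in mt−, while the median widths were 788 and 822 bp for H3K4me3 and 707 and 706 bp for H3K9me1. H3K9me3 peaks were also narrow and numerous, with 12026 in mt+ and 12430 in mt−. H3K4me1 gave 2067 and 5151 peaks, with the lowest median folds of the 4 marks in WT (2.11 and 2.00).

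The first comparison asked which peaks of each mark were absent when DNMT1 was knocked out. Most of the broad H3K9me1 signal of WT cells was missing from the dnmt1 lists. The covered length was 0.982 Mb in dnmt1 mt+ and 1.77 Mb in dnmt1 mt−, which is 13.1% and 22.3% of the WT length. Wide peaks numbered 18 and 32, against 282 and 308 in WT. In mt+, 391 of 3831 WT peaks were kept (10.2%, 95% interval 9.29 to 11.2), and in mt− 657 of 4113 (16.0%, 14.9 to 17.1). Chance overlap was lower, with a median of 2.82% and 5.20% and a highest value of 5.35% and 7.71% over 1000 shifts. For scale, 81.2% (79.9 to 82.4) of WT mt+ peaks were found again in WT mt−.

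**Figure D1:**
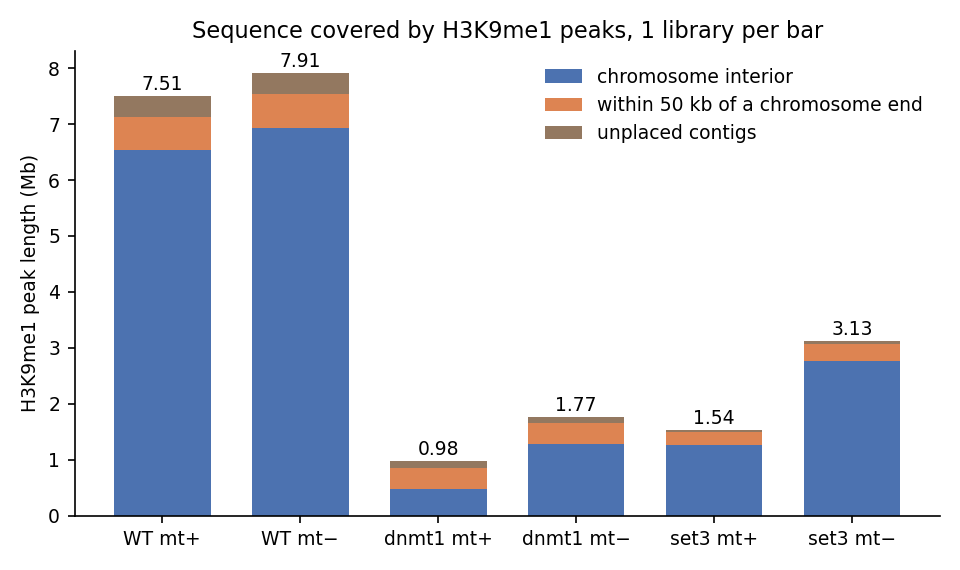
Sequence covered by H3K9me1 peaks in each of the 6 libraries (vertical axis, Mb), split into chromosome interiors, the outermost 50 kb of each chromosome end and unplaced contigs; 1 library per bar, no error bars. The WT bars reach 7.51 and 7.91 Mb and the mutant bars 0.982 to 3.13 Mb, and the part at chromosome ends shrinks less than the interior part in both mutants.

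Large interior domains held little H3K9me1 in dnmt1, as did interiors as a whole. The length covered in chromosome interiors was 7.17% of WT in dnmt1 mt+ and 18.4% in dnmt1 mt−. There were 87 wide H3K9me1 intervals in WT cells, spread over 17 chromosomes and together 5.83 Mb long. Averaged by length, H3K9me1 peaks covered 71.9% of them in WT mt+ and 75.7% in WT mt−, against 4.96% in dnmt1 mt+ and 12.6% in dnmt1 mt−. In dnmt1 mt+, 40 of the 87 intervals held no H3K9me1 peak at all, and in dnmt1 mt− 21. The widest interval lay on chromosome 16 from 3294760 to 3578255. Its coverage was 85.3% in WT mt+ and 87.7% in WT mt−, and 7.04% and 21.4% in the corresponding dnmt1 libraries. On chromosome 6, the interval from 4348515 to 4627189 was covered to 87.4% and 86.4% in WT and to 5.497% and 15.9% in dnmt1. The interval on chromosome 11 from 2867411 to 3025066 went from 88.2% and 86.5% to 1.48% and 16.0%. The interval on chromosome 12 from 815302 to 1051184 had 69.3% and 64.1% in WT and 0.183% and 2.33% in dnmt1. Over the 12 widest intervals, each at least 141 kb long, coverage ranged from 47.7% to 91.2% in WT mt+ and from 0% to 7.52% in dnmt1 mt+, and from 56.8% to 91.1% in WT mt− and from 0.368% to 24.2% in dnmt1 mt−. The only 1 of the 87 covered to over 50% in dnmt1, picked out after its values were seen, was the interval on chromosome 13 from 4368391 to 4416730, with 94.9% and 91.2% in WT and 75.3% and 72.3% in dnmt1. The next highest in dnmt1 mt− was that on chromosome 2 from 2588904 to 2649412, with 42.6% against 93.3% in WT mt−. The interval on chromosome 6 from 234607 to 260608 had more in dnmt1 mt+ than in WT mt+, 1.93% against 1.48%.

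Among single peaks, 3097 WT mt+ H3K9me1 peaks overlapped neither dnmt1 list, and 2360 of them had a counterpart of the same kind in mt−. Shifted lists gave a median of 268. However, 81.2% of all WT mt+ peaks lay at a WT mt− peak, and most peaks of each strain were lost. The number therefore does not show agreement in loss beyond the agreement of the WT lists. The 12 of the 2360 ranked highest by the authors' fold had folds of 5.47 to 6.33 in mt+ and 5.04 to 5.74 in mt−. The first lay on chromosome 3 from 645135 to 651624, with a fold of 6.33 in mt+ and 5.52 in mt−. Others were on chromosome 16 from 782972 to 784407 (6.04 and 5.60), on chromosome 8 from 2628932 to 2633971 (6.01 and 5.32), and on chromosome 9 from 1884987 to 1896798 (5.47 and 5.49). Gained H3K9me1 peaks shared by both dnmt1 strains numbered 74, against a chance median of 3. They were narrow and weak, and the 12 ranked highest had folds of 2.26 to 2.83 in mt+ and were 0.242 to 1.22 kb wide. Of all dnmt1 mt+ H3K9me1 peaks, 66.2% were found in dnmt1 mt−. The 74 therefore do not show agreement in gain beyond that of the lists.

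**Figure D2:**
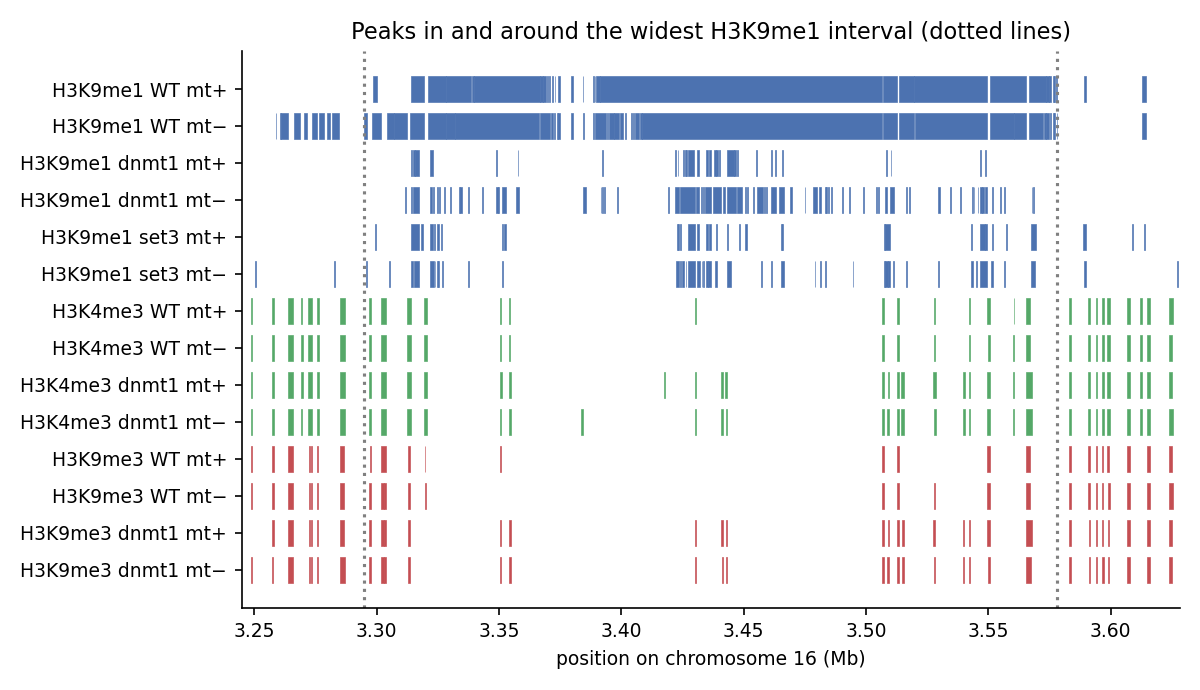
Peaks (blocks) along chromosome 16 in and around the widest WT H3K9me1 interval, between the dotted lines at 3294760 and 3578255; the horizontal axis is position in Mb and each row is 1 library. H3K9me1 covers 85.3% and 87.7% of the interval in WT and 7.04% to 21.4% in the 4 mutant libraries, while H3K4me3 peaks in it number 14 and 13 in WT and 20 and 20 in dnmt1.

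Most of the broad H3K9me1 signal of WT cells was also missing from the set3 lists. The set3 lists covered 1.54 Mb in mt+ and 3.13 Mb in mt−, 20.5% and 39.5% of the WT length. Only 6 and 7 peaks were 5 kb or wider. Of the WT peaks, 518 were kept in mt+ (13.5%, 12.5 to 14.6) and 720 in mt− (17.5%, 16.4 to 18.7), against chance medians of 5.09% and 9.92%. The 87 wide intervals were covered to 7.32% in set3 mt+ and 9.85% in set3 mt−. The chromosome 11 interval named above had 0.412% in set3 mt+ and 0% in set3 mt−. The chromosome 16 interval had 8.68% and 11.8%. The highest-ranked peak lost from set3 in both strains was the 1.44 kb peak on chromosome 16 from 782972, also among those lost from dnmt1. The widest of the 12 ranked highest, on chromosome 11 from 2890079 to 2925013, was 34.9 kb long and had a fold of 5.95 in WT mt+. With a −log10 q of at least 5, the set3 length was 11.5% of WT in mt+ and 20.9% in mt−.

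Unlike the dnmt1 lists, the set3 lists were dominated by new narrow peaks. In set3 mt+, 1602 peaks (57.5% of the list) overlapped no WT H3K9me1 peak of either strain, and in set3 mt− 4552 (73.9%). Their median width was 362 and 351 bp. Between the strains, 811 were shared, against a chance median of 54 and a highest value of 112. The one ranked highest lay on chromosome 1 from 7513879 to 7514569 in mt+, with a fold of 3.30, and was overlapped in mt− by a peak with a fold of 3.09. Another covered chromosome 6 from 5922319 to 5924977 (3.11 in mt+, 3.15 in mt−). Of all set3 mt+ peaks, 63.5% were found in set3 mt−. The 811 shared new peaks therefore do not show agreement in gain beyond that of the lists. Most WT peaks were lost from each mutant, so a large number lost from both is given by the loss rates alone. In mt+, 3161 WT peaks were lost from both dnmt1 and set3, where independent losses would give 2975, and 239 were kept in both, where independence would give 52.9. In mt− the numbers were 3158 against 2851 lost and 422 against 115 kept. Both mutants were compared with the same WT list, so part of the excess may come from that shared list, and no simulation of unchanged libraries was possible without replicates.

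**Figure D3:**
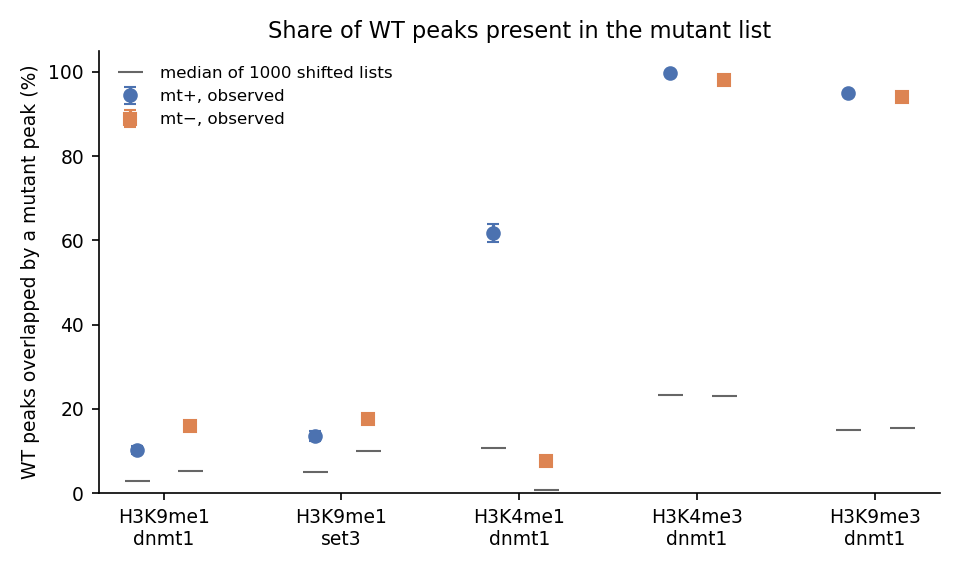
Share of WT peaks (vertical axis, %) overlapped by at least 1 bp in the mutant list of the same strain, for each mark and mutant; circles are mt+, squares mt−, error bars are Wilson 95% intervals for counting error only, and dashes are the median of 1000 circularly shifted lists. H3K9me1 lies between 10.2% and 17.5%, H3K4me3 at 99.8% and 98.2%, H3K9me3 at 94.9% and 94.0%, and H3K4me1 at 61.8% in mt+ and 7.71% in mt−.

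Chromosome ends kept more H3K9me1 than interiors did. Within 50 kb of the ends, 52.2% of the WT base pairs were kept in dnmt1 mt+ and 62.6% in dnmt1 mt−. In set3 the shares were 38.7% and 46.5%. In chromosome interiors the shares were 5.18% and 12.1% in dnmt1 and 8.54% and 11.1% in set3. On contigs they were 33.8% and 29.3% in dnmt1 and 9.78% and 16.9% in set3. The low interior share held on each of the 17 chromosomes, ranging from 2.00% to 16.4% in dnmt1 mt+, from 5.37% to 20.8% in dnmt1 mt−, from 3.52% to 13.8% in set3 mt+ and from 4.08% to 21.8% in set3 mt−, with chromosome 13 highest in each. That chromosome holds the interval from 4368391 to 4416730 named above, covered to 75.3%, 72.3%, 42.9% and 60.4% in the same order. Its rank therefore need not hold for the rest of the chromosome. The left end of chromosome 17 had 34.4 kb of H3K9me1 in WT mt+, 30.3 kb in dnmt1 and 25.6 kb in set3. At the right end of chromosome 9 the corresponding values were 17.3, 16.3 and 17.2 kb. The right end of chromosome 12 went the other way, from 22.8 kb in WT mt+ to 0 kb in both mutants. Of 27 end windows with at least 5 kb in WT mt+, 13 had at least 50% of that length in dnmt1 and 7 in set3, at the same places or not. Of 29 in mt−, 19 had as much in dnmt1 and 15 in set3. The local background at summits was higher at ends than in interiors (a scaled pileup of 38 against 35 in WT mt+ and 41 against 37.1 in WT mt−). The gap was wider in the mutant lists, with 30.8 against 22.6 in dnmt1 mt+, 50.8 against 39 in dnmt1 mt−, 27 against 20.5 in set3 mt+ and 28 against 21.9 in set3 mt−. At 3 ends, described further below, dnmt1 mt+ had over 5 kb more than WT.

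H3K4me3 and H3K9me3 peaks were almost all retained in dnmt1. Of the H3K4me3 peaks, 15229 of 15256 were kept in mt+ (99.8%, 99.7 to 99.9) and 15148 of 15433 in mt− (98.2%, 97.9 to 98.4). Of the H3K9me3 peaks, 11415 of 12026 were kept in mt+ (94.9%, 94.5 to 95.3) and 11690 of 12430 in mt− (94.0%, 93.6 to 94.4). These shares were close to those between the 2 WT strains, 99.4% for H3K4me3 and 96.7% for H3K9me3. Chance overlap had a median of 23.3% and 23.1% for H3K4me3, and of 14.98% and 15.6% for H3K9me3.

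The few gained peaks lay to a large extent where WT cells carried H3K9me1. In dnmt1 mt+, 216 of 560 gained H3K4me3 peaks (38.6%, 34.6 to 42.7) overlapped a WT H3K9me1 peak of the same strain, against 428 of 15114 kept peaks (2.83%), with an odds ratio of 21.5 and an adjusted p of 3.31e-160 by Fisher's exact test. In dnmt1 mt− it was 154 of 252 (61.1%, 54.97 to 66.9) against 3.15%, with an odds ratio of 48.3 and an adjusted p of 5.88e-152 by the same exact test. For H3K9me3, 292 of 850 gained peaks in mt+ (34.4%, 31.2 to 37.6) and 353 of 777 in mt− (45.4%, 42.0 to 48.9) did so, against 2.18% and 2.198% of the kept peaks. The odds ratios were 23.4 and 37.0, with adjusted p of 5.55e-206 and 9.55e-290 by Fisher's exact test. In the 87 wide intervals, H3K4me3 peaks numbered 462 and 512 in WT and 630 and 621 in dnmt1, and H3K9me3 peaks 317 and 323 in WT and 438 and 465 in dnmt1. Of these H3K9me3 peaks, 6 and 34 in dnmt1 and 0 in WT lay in the chromosome 13 interval from 4368391 to 4416730. That interval kept most of its H3K9me1 in dnmt1. Away from H3K4me3 peaks, 195 and 246 dnmt1 H3K9me3 peaks overlapped a WT H3K9me1 peak, and 181 and 231 a dnmt1 one. A gain at a WT H3K9me1 peak therefore need not lie where H3K9me1 was lost. With the H3K9me1 peaks of both WT lists joined over gaps of up to 5 kb, an alternative added after the data were examined, the odds ratios of gained peaks were lower, 14.0 and 27.3 for H3K4me3 and 10.04 and 16.1 for H3K9me3, with the highest adjusted p of the 4 at 4.37e-126 by the exact test. Lost peaks overlapped a WT H3K9me1 peak more often than kept ones in 3 of 6 tests. For H3K4me3 it was 5 of 27 lost peaks in mt+ (odds ratio 8.38, adjusted p 9.83e-04 by Fisher's exact test) and 24 of 285 in mt− (2.67, adjusted exact p 9.45e-05). For H3K9me3 it was 29 of 611 in mt+ (2.28, adjusted exact p 3.54e-04) and 21 of 740 in mt− (1.22, adjusted exact p 0.381). For H3K4me1 it was 75 of 790 in mt+ (1.21, adjusted exact p 0.281) and 257 of 4754 in mt− (0.675, adjusted exact p 0.0631). With joined peaks, all 4 tests of lost H3K4me3 and H3K9me3 peaks passed, with odds ratios of 1.37 to 4.83 and a highest adjusted exact p of 0.0334, and lost H3K4me1 peaks in mt− lay there less often than kept ones (0.638, adjusted exact p 0.0168). Gained H3K4me1 peaks overlapped a WT H3K9me1 peak less often than kept ones, at 2.95% against 8.54% in mt+ (odds ratio 0.325, adjusted exact p 7.76e-19) and 4.26% against 7.77% in mt− (0.528, adjusted exact p 0.0255). With a −log10 q of at least 5 the odds ratio was 0.211 in mt+. In mt− it was then 2.73, from 2 of 13 gained and 1 of 16 kept peaks (unadjusted exact p 0.573). These tests were not in the plan made beforehand, compare 2 libraries and treat neighbouring peaks as independent. Counted against both WT strains, the share of gained peaks at WT H3K9me1 peaks ranged from 54.99% to 69.5% over the 4 comparisons.

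Gained peaks recurred between the strains. Of 300 H3K4me3 peaks of dnmt1 mt+ without a WT peak of either strain, 170 were shared with dnmt1 mt−, against a chance median of 0 and a highest value of 7, and 138 of these overlapped H3K9me1 peaks of both WT strains. For H3K9me3, 269 of 481 were shared, against a chance median of 6, and 191 overlapped such peaks. All 12 of the highest-ranked gained peaks of each mark did so. Shifted lists do not carry the general agreement of the 2 dnmt1 lists. Of all dnmt1 mt+ peaks, 97.6% for H3K4me3 and 95.1% for H3K9me3 were found in dnmt1 mt−. The shared gains therefore do not show agreement in gain beyond that of the lists. The gained H3K4me3 peak ranked first was on chromosome 3 from 6978659 to 6980123, with a fold of 6.20 in mt+ and 4.70 in mt−. At the same place H3K9me3 was gained from 6978693 to 6979982 (4.83 and 3.74). On chromosome 10, H3K4me3 was gained from 3631257 to 3632495 (5.499 and 4.63) and H3K9me3 from 3631363 to 3632390 (4.39 and 5.88). The highest-ranked H3K9me3 gain lay on chromosome 13 from 4324001 to 4325183 (5.18 and 6.32). On chromosome 16, H3K4me3 was gained from 3442523 to 3443272 (5.93 and 4.14), inside the widest H3K9me1 interval. H3K4me3 peaks lost in both strains numbered 8, of which 3 overlapped H3K9me1 peaks of both WT strains, and the strongest was on chromosome 3 from 8883927 to 8884690 (5.59 and 3.30). H3K9me3 peaks lost in both strains numbered 123, of which 2 overlapped H3K9me1 peaks of both WT strains.

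More H3K9me3 lay at chromosome ends in dnmt1 than in WT. The length covered within 50 kb of the ends was 76.7 kb in WT mt+ and 82.3 kb in WT mt−, and 173 kb and 212 kb in dnmt1. H3K9me3 peaks away from any H3K4me3 peak numbered 53 of 12026 in WT mt+ (0.441%, 0.337 to 0.576) and 33 of 12430 in WT mt− (0.265%, 0.189 to 0.373). In dnmt1 there were 206 in mt+ (1.69%, 1.47 to 1.93) and 278 in mt− (2.23%, 1.99 to 2.50). Of these, 154 and 145 lay at chromosome ends, and 181 and 231 overlapped an H3K9me1 peak of the same dnmt1 strain. In WT, 38 of the 53 and 14 of the 33 lay at ends, and 42 and 16 overlapped a WT H3K9me1 peak of the strain. Such a location was thus not particular to dnmt1.

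H3K4me1 lists varied most in length, and dnmt1 differed from WT in opposite directions in the 2 strains. There were 12718 peaks in dnmt1 mt+ against 2067 in WT, and 1104 in dnmt1 mt− against 5151 in WT. In mt+, 61.8% of WT peaks were kept (59.7 to 63.9, chance median 10.6%), and in mt− 7.71% (7.01 to 8.47, chance median 0.757%). The 2 WT strains shared 33.8% (31.8 to 35.8) of the mt+ peaks. With both lists of a pair reduced to the shorter length, the kept share was 18.6% in mt+ and 12.6% in mt−. Peaks gained in both dnmt1 strains numbered 314, against a chance median of 42. The highest-ranked was on chromosome 9 from 2906127 to 2906706, with folds of 2.43 and 2.33, and 0 of the 12 ranked highest overlapped H3K9me1 peaks of both WT strains. Of all dnmt1 mt− H3K4me1 peaks, 66.7% were found in dnmt1 mt+. The 314 shared gains therefore do not show agreement in gain beyond that of the lists.

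The sex-determining region was examined as the first 1 Mb of chromosome 6 and as the sequence named mating_type_plus, at least 365 kb long. No gene coordinates on this build were at hand to place the region, and mating_type_plus was taken as the mt+ locus from its name alone. The peak lists of the 2 strains differed in both places. On mating_type_plus, H3K4me3 peaks numbered 27 in WT mt+ and 31 in dnmt1 mt+, against 9 and 10 in the mt− libraries. In the first 1 Mb of chromosome 6 they numbered 151 and 160 in mt+ and 211 and 198 in mt−. H3K9me1 in this part of chromosome 6 covered 36.4 kb in WT mt+ and 114 kb in WT mt−, which ranked at the 59.0th and the 79.9th percentile of 1 Mb windows. In dnmt1 the H3K9me1 length there was 3.49 kb in mt+ and 13.6 kb in mt−, and in set3 8.61 and 54.3 kb, the last at the 94.7th percentile of its own list. The H3K4me3 length of this region ranked at the 26.2nd percentile in WT mt+, the 97.8th in WT mt− and the 95.5th in dnmt1 mt−, and on mating_type_plus at the 2.06th in WT mt+ and the 0.280th in WT mt− of windows of the same length.

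Of the 7 H3K9me1 intervals of the chromosome 6 region, 2 were empty in all 4 mutant libraries. The interval from 158297 to 175561 held 10.8 kb of H3K9me1 in WT mt+ and 12.3 kb in WT mt−, and 0 kb in both dnmt1 libraries and set3 mt+, with 0.257 kb in set3 mt−. The interval from 184483 to 202131 held 7.56 and 16.3 kb in WT and 0 kb in all 4 mutant libraries, and that from 383430 to 397144 held 9.73 and 9.21 kb in WT and 0 kb in all 4 mutant libraries. The interval from 482311 to 525110 held H3K9me1 peaks mainly in mt−, with 3.97 kb in WT mt+ and 33.8 kb in WT mt−, 5.21 kb in dnmt1 mt− and 12.6 kb in set3 mt−. The widest, from 745622 to 789000, held 0 kb in WT mt+ and 23.0 kb in WT mt−. It held 0.504 kb in dnmt1 mt− and 12.7 kb in set3 mt−. The interval from 13729 to 25441 held 1.34 and 6.72 kb in WT and 0.295 to 0.545 kb in the mutants. That from 234607 to 260608 held 0.386 kb in WT mt+ and 0.501 kb in dnmt1 mt+, and 4.38 kb in WT mt−, 0.885 kb in dnmt1 mt− and 3.19 kb in set3 mt−. H3K4me3 peaks in it numbered 0 in WT and dnmt1 mt+ and 19 in WT and dnmt1 mt−. Whether sequence of the chromosome 6 region is absent from mt+, or its reads map elsewhere, was not examined. A strain difference here therefore need not be a difference in a mark. On mating_type_plus, the interval from 221915 to 227033 held 4.13 kb in WT mt+ and 3.14 kb in WT mt−, 0 kb in dnmt1 mt+ and 1.45 kb in set3 mt+.

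**Figure D4:**
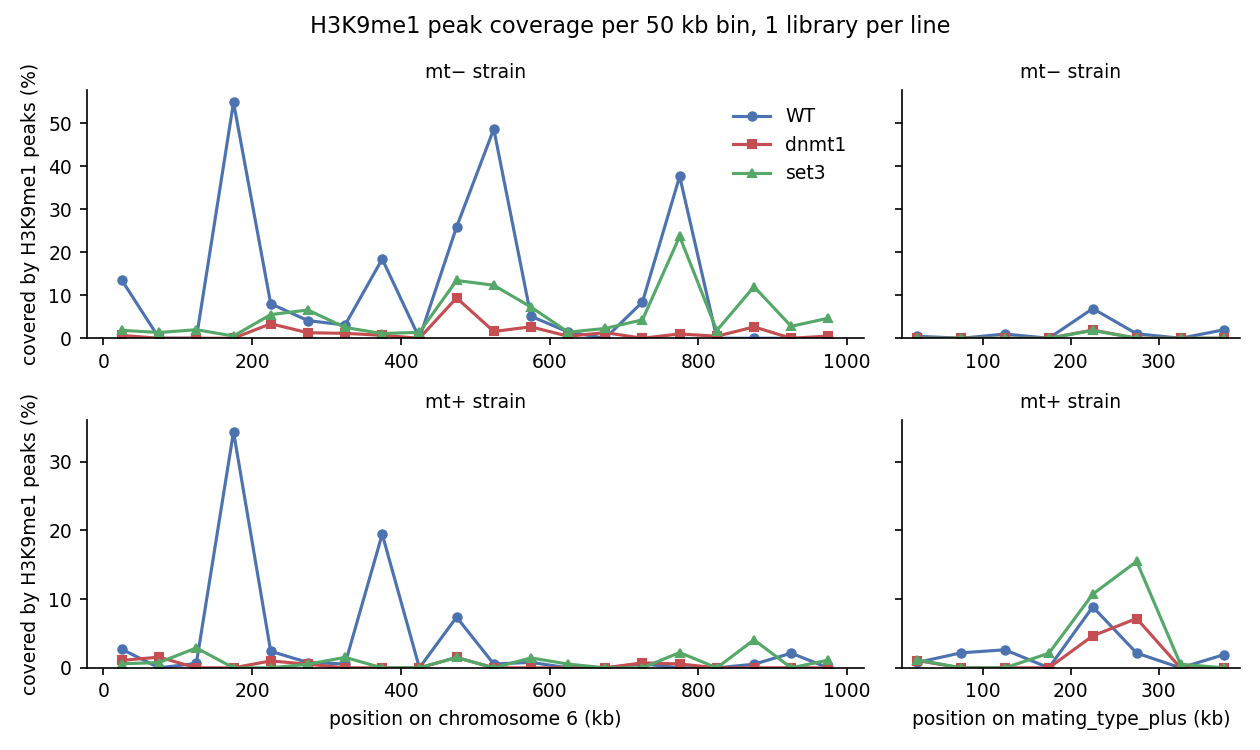
Share of each 50 kb bin covered by H3K9me1 peaks (vertical axis, %) along the first 1 Mb of chromosome 6 (left) and along mating_type_plus (right), for the mt− strain (top) and the mt+ strain (bottom); each line is 1 library. The bins from 500 to 550 kb and from 750 to 800 kb of chromosome 6 are covered to 48.6% and 37.6% in WT mt−, to 1.57% and 1.01% in dnmt1 mt− and to 12.3% and 23.7% in set3 mt−.

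The share of peaks lost in the region differed from that elsewhere in 2 of 20 tests, 1 for H3K9me1 and 1 for H3K4me3. In dnmt1 mt−, 10 of 83 WT H3K9me1 peaks of the chromosome 6 region were kept (12.05%, 6.68 to 20.8), against 16.1% elsewhere, with an adjusted p of 1 by Fisher's exact test. In dnmt1 mt+ it was 2 of 29 (6.90%, 1.91 to 22.0) against 10.2%, also with an adjusted p of 1 by the exact test. In set3 mt−, 41 of 83 were kept (49.4%, 38.9 to 59.9) against 16.8% elsewhere, with an adjusted p of 3.38e-10 by Fisher's exact test. Of these, 26 lay in the interval from 745622 to 789000, and without that interval 15 of 50 were kept (30.0%, 19.1 to 43.8), with an exact p of 0.0213, or 0.311 after adjustment. In dnmt1 mt−, 193 of 211 H3K4me3 peaks of the region were kept (91.5%, 86.9 to 94.5) against 98.2% elsewhere, with an adjusted p of 7.59e-07 by the exact test. Of the 18 that were lost, 12 lay in the same interval, and without it the exact p was 0.143, or 0.716 after adjustment. On mating_type_plus, with 1 to 27 WT peaks per comparison, no kept share passed the adjusted test. The lowest p was for H3K9me1 in set3 mt+, with 5 of 14 kept (35.7%) against 13.4% elsewhere, 0.0311 by Fisher's exact test and 0.208 after adjustment. There the H3K9me1 peaks numbered 14 in WT mt+, 16 in dnmt1 mt+ and 22 in set3 mt+, covering 8.60, 6.44 and 14.998 kb.

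Libraries of one genotype were also compared between mt+ and mt−, which sets the scale for the genotype differences. For H3K4me3, 99.4% of WT mt+ peaks and 97.6% of dnmt1 mt+ peaks were found in the mt− list. For H3K9me3 the shares were 96.7% and 95.1%. For H3K9me1 they were 81.2% in WT, 66.2% (63.5 to 68.8) in dnmt1 and 63.5% (61.7 to 65.3) in set3. For H3K4me1 they were 33.8% in WT and 5.80% (5.41 to 6.22) in dnmt1. The 5.80% is limited by list length, since 12718 mt+ peaks were looked up among 1104 mt− peaks. In reverse, 13.8% of WT mt− and 66.7% of dnmt1 mt− H3K4me1 peaks were found in the mt+ list. With both lists reduced to the shorter length, 17.03% (WT) and 12.6% (dnmt1) of mt+ H3K4me1 peaks were found in mt−. The 5.80% alone therefore sets no scale for H3K4me1. Strain, mating type and library differ together in these pairs.

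H3K9me3 peaks lay at H3K4me3 peaks, and the other 2 marks mostly did not. In WT mt+, 99.6% (99.4 to 99.7) of H3K9me3 peaks lay at an H3K4me3 peak, against a chance median of 20.4%, and 77.0% of H3K4me3 peaks lay at an H3K9me3 peak. In WT mt− these shares were 99.7% and 78.3%, and in dnmt1 98.3% and 75.1% in mt+ and 97.8% and 77.0% in mt−. H3K4me1 avoided H3K4me3: 4 of 2067 peaks in WT mt+ (0.194%) and 14 of 5151 in WT mt− (0.272%) overlapped one, against chance medians of 16.7% and 17.5%. H3K9me1 peaks overlapped H3K4me3 peaks less often than shifted lists did, at 10.4% against 26.2% in WT mt+ and 12.4% against 26.9% in WT mt−. In WT, H3K4me1 lay at H3K9me1 about as often as shifted lists did, with 8.56% against a chance median of 6.63% and a highest value of 8.95% in mt+, and 5.59% against a median of 7.07% in mt−. In dnmt1 it did so more often than the shifted lists, with 2.10% against a median of 1.15% and a highest value of 1.51% in mt+, and 10.9% against 2.08% and 4.08% in mt−. For H3K9me1 at H3K4me3 in dnmt1 the overlap was 0.962% against 19.0% in mt+ and 1.07% against 18.2% in mt−.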

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

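The tests of missing sequence, of weaker enrichment at all sites and of a shared input bias were chosen only after the results they bear on were seen, and the others before. None of the differences between the strains below was tested, because each strain has 1 library per condition.

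The dnmt1 and WT libraries differed in opposite directions in the 2 strains for H3K4me1. The ratio of dnmt1 to WT was 6.15 for the number of peaks and 8.39 for the covered length in mt+, and 0.214 and 0.187 in mt−. A different depth of the peak calls is a candidate technical source. At the working background and lowest p-value of the shorter list, 9008 of the 12718 dnmt1 mt+ peaks would still pass, against 2067 seen in WT, and 4403 of the 5151 WT mt− peaks, against 1104 seen in dnmt1 mt−, which argues against depth as the whole source in either strain. A different efficiency of the H3K4me1 precipitation stays open, since there is 1 library each. Few WT peaks also reached a −log10 q of at least 5 (39 of 2067 in mt+ and 62 of 5151 in mt−). An effect of DNMT1 that differs between strains was not tested.

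The following ratios also went in opposite directions in the 2 strains. For set3, the number of H3K9me1 peaks relative to WT was 0.727 in mt+ and 1.498 in mt−. The covered length of H3K4me3 in dnmt1 relative to WT was 1.06 in mt+ and 0.969 in mt−. The covered length of H3K9me3 in dnmt1 relative to WT was 1.04 in mt+ and 0.999 in mt−.

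The shorter H3K9me1 length in both mutants was weighed against 3 technical explanations. If the mutant calls had only been shallower, WT peaks holding 98.0% of the WT length would still pass at the dnmt1 mt+ depth. The shares were 99.7% at dnmt1 mt−, 98.4% at set3 mt+ and 98.9% at set3 mt−, while 13.1%, 22.3%, 20.5% and 39.5% were seen. This prediction keeps a WT peak at full width if its summit passes, so it does not cover narrowing. By number, 92.0%, 99.5%, 93.9% and 95.9% of WT peaks would pass, against 10.2%, 16.0%, 13.5% and 17.5% kept, which argues against depth for the lost peaks. The dnmt1 mt− call was not shallower, with a working background of 34.2 against 32.0 in WT mt−. Missing or unmappable sequence in dnmt1 should deplete other marks in the joined WT H3K9me1 intervals, but H3K4me3 peaks there were 1.26 times as many as in WT in mt+ and 1.09 times in mt− and H3K9me3 peaks 1.37 and 1.44 times, which argues against it over these intervals as a whole, although H3K4me1 peaks were 2.71 and 0.216 times as many beside 6.15 and 0.214 for the whole lists, shorter stretches stay open, and set3 has no other mark to test this. If enrichment were weaker by a single factor at all sites, ends and interiors should keep similar shares at matched WT −log10 p, whereas ends kept 8.77 (dnmt1 mt+), 4.52 (dnmt1 mt−), 3.82 (set3 mt+) and 3.78 (set3 mt−) times the interior share, but without the strongest of 5 classes the ratios were 4.83 (95% interval 1.22 to 15.7), 4.01 (2.01 to 7.01), 2.59 (0.905 to 5.96) and 1.84 (0.844 to 3.82), and the background at ends relative to interiors was 1.16 to 1.25 times as high in the mutant lists as in WT. With that gap, 1 factor set to the interior share predicts 22.4%, 34.6%, 29.2% and 37.4% of end peaks kept. Seen were 43.4%, 52.5%, 32.0% and 34.6%. For base pairs, with the factor set anew, 20.1%, 2.84%, 16.7% and 3.00% are predicted, against 51.7%, 62.3%, 38.4% and 46.1% seen. That prediction again keeps a peak at full width if its summit passes, while the share seen counts parts of peaks. The predicted and seen base pairs are therefore not like measures. Weaker precipitation and a loss of H3K9me1 in the mutants thus cannot be told apart with 1 library each.

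Nearly all H3K9me3 peaks lay at H3K4me3 peaks. A bias of the shared input or of fragmentation at these sites could also draw H3K4me1 peaks there. At most 0.527% of H3K4me1 peaks lay at H3K4me3 peaks in the 4 combinations of strain and genotype, where chance gave at least 16.5%. Both marks are methylation states of lysine 4 of histone H3, so H3K4me1 may be scarce there with or without a bias. The test therefore cannot decide. Recognition of H3K4me3-marked nucleosomes by the H3K9me3 antibody would make the 2 folds rise together. Across H3K9me3 peaks at H3K4me3 peaks, which are not independent replicates, Spearman's rho was 0.488 in WT mt+ and 0.293 in WT mt−, the latter just under the 0.3 set beforehand for both WT strains, and 0.397 and 0.408 in dnmt1 mt+ and mt−, both above it. Cross-recognition, a shared bias and true co-occurrence therefore cannot be told apart with these lists, and no biological explanation was tested.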

How the results depend on the processing

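The alternatives of base pair shares, of H3K9me1 lengths with stricter peaks, of end windows of 100 kb, of the chromosome 6 region without its widest interval and of gained peaks under other definitions were chosen after the data were examined, and the others before. A share counts as moved when it leaves the 95% interval of the value in the report, and a count, a length or a share kept at ends or interiors when it changes by over 1.5 times. Each result was compared with its value under each alternative. Under the alternatives set before the data were examined, 74 comparisons moved and 56 stayed the same. These include the peak counts on mating_type_plus, a sequence chosen only after the data were examined. Under the alternatives chosen later, 30 comparisons moved, 14 stayed the same and 2 no longer passed their test. The order of the mutants in the share of WT H3K9me1 peaks kept depended on the alternative, with set3 above dnmt1 in the report's values. By base pairs in mt−, dnmt1 kept more (16.7% against 14.1%). With lists of equal length dnmt1 kept more in both strains, but lengths were matched only within a pair (1248 and 2716 peaks for dnmt1, 2785 and 4113 for set3). With stricter peaks in both mt− lists, dnmt1 kept 12.8% (11.7 to 13.9) and set3 12.6% (11.6 to 13.7), which hardly differ. In the first 1 Mb of chromosome 6, H3K9me1 peaks numbered 113 in set3 mt− against 83 in WT mt−, but 62 against 73 with a −log10 q of at least 5. With the region widened by 100 kb, all 10 counts stayed within 1.5 times, 1 of them unchanged, and the 8 shares of H3K9me1 kept at ends or interiors changed by less than 1.5 times with end windows of 100 kb, though each end share was lower (45.3% and 54.8% in dnmt1, 34.1% and 40.99% in set3). The cause of a move was not tested, except that stricter or shorter lists hold fewer peaks by construction. With WT and mutant libraries paired by strain, an analysis added later, the log2 ratio to WT of the H3K9me1 length was −2.55 in dnmt1 (95% interval −4.08 to −1.01) and −1.81 in set3 (−3.35 to −0.278), on 2 residual degrees of freedom. For the number of H3K9me1 peaks it was −1.11 (−2.92 to 0.703) and 0.0613 (−1.75 to 1.87). For the length of the other marks in dnmt1, on 1 degree of freedom, it was 0.325 for H3K4me1 (−34.5 to 35.2), 0.0227 for H3K4me3 (−0.841 to 0.887) and 0.0281 for H3K9me3 (−0.354 to 0.410). All these intervals take the disagreement between the strains as error, so each strain stands in for a replicate. For H3K9me1 that error is pooled over dnmt1 and set3, so the intervals are not those of each mutant alone. They are not a test between genotypes. Peaks by gene feature, genes with a peak and gene lists were not run, since no annotation on the build of the peak lists was at hand. The lists hold only peaks past the authors' threshold, so signal below it, which matters most for H3K4me1 with only 39 and 62 WT peaks at a −log10 q of at least 5, was not seen. In all pairs below, mt+ comes first and mt− second.

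When at least 50% of the shorter peak had to overlap, the dnmt1 lists kept 53.6% and 6.37% of WT H3K4me1 peaks. Of mt+ peaks, the mt− list then held 26.5% for H3K4me1 in WT, 5.02% for H3K4me1 in dnmt1 and 57.99% for H3K9me1 in set3. H3K4me1 lay at H3K4me3 for 0% and 0.0194% of peaks in WT and 0.0157% and 0% in dnmt1, and H3K9me1 for 3.24% and 4.18% in WT and 0.0801% and 0% in dnmt1.

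With a −log10 q of at least 5 in both lists, dnmt1 kept 33.3% and 12.9% of H3K4me1, 7.81% and 12.8% of H3K9me1 and 93.98% and 93.2% of H3K9me3, and set3 kept 9.26% and 12.6% of H3K9me1. The mt− list held 12.8% (WT) and 1.56% (dnmt1) of mt+ peaks for H3K4me1, 82.6% (WT) and 59.9% (set3) for H3K9me1, and 98.9% (WT) and 97.2% (dnmt1) for H3K4me3. H3K9me3 lay at H3K4me3 for 99.7% and 99.6% in WT and 99.1% and 98.3% in dnmt1, H3K4me1 for 5.13% and 1.61% in WT and 1.56% and 3.45% in dnmt1, and H3K9me1 for 2.07% in dnmt1 mt−. The set3 length of H3K9me1 was 11.5% and 20.9% of WT. H3K9me1 peaks on mating_type_plus numbered 8 in WT mt+, 9 in dnmt1 mt+ and 11 in set3 mt+, and in the first 1 Mb of chromosome 6 they numbered 10 in dnmt1 mt−, 11 in set3 mt+ and 62 in set3 mt−.

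With both lists reduced to the length of the shorter one, dnmt1 kept 18.6% and 12.6% of H3K4me1, 21.7% and 20.99% of H3K9me1, 98.8% and 97.7% of H3K4me3 and 94.3% of H3K9me3 in mt+, and set3 kept 15.5% and 14.6% of H3K9me1. The mt− list held 17.03% (WT) and 12.6% (dnmt1) of mt+ peaks for H3K4me1, 78.9% (WT), 54.97% (dnmt1) and 44.9% (set3) for H3K9me1, 98.8% (WT) and 98.2% (dnmt1) for H3K4me3, and 95.2% (WT) and 93.997% (dnmt1) for H3K9me3.

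With only the first list made stricter, dnmt1 kept 82.1% and 19.4% of H3K4me1, 99.9% and 98.8% of H3K4me3 and 95.7% and 94.9% of H3K9me3. The mt− list held 58.97% (WT) and 13.7% (dnmt1) of mt+ peaks for H3K4me1, 84.9% (WT), 77.2% (dnmt1) and 78.5% (set3) for H3K9me1, 98.1% (dnmt1) for H3K4me3, and 97.5% (WT) and 96.5% (dnmt1) for H3K9me3.

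Counted as base pairs, dnmt1 kept 49.7% and 5.02% of H3K4me1, 98.7% and 94.1% of H3K4me3 and 90.9% and 88.6% of H3K9me3, and set3 kept 10.98% and 14.1% of H3K9me1. The mt− list held 23.8% (WT) and 3.22% (dnmt1) of mt+ base pairs for H3K4me1, 89.7% (WT), 69.9% (dnmt1) and 60.2% (set3) for H3K9me1, 98.1% (WT) and 93.7% (dnmt1) for H3K4me3, and 93.2% (WT) and 90.01% (dnmt1) for H3K9me3.

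Without the widest interval of the chromosome 6 region, the adjusted p of Fisher's exact test was 0.716 for H3K4me3 in dnmt1 mt− and 0.311 for H3K9me1 in set3 mt−, both no longer past the threshold. Of gained peaks with a −log10 q of at least 5, 44.1% and 71.6% overlapped WT H3K9me1 peaks for H3K4me3, and 30.9% for H3K9me3 in mt+. Against both WT strains the shares were 56.7% and 69.5% for H3K4me3 and 56.8% and 54.99% for H3K9me3, and with the H3K9me1 peaks of both WT lists joined 50.4% and 67.5% for H3K4me3 and 39.2% and 49.9% for H3K9me3.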

Other observations

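All comparisons in this part were chosen after the data were examined, and their cause was not tested.

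In the widest H3K9me1 interval of the chromosome 6 region, from 745622 to 789000, peaks recurred at a regular distance in WT mt−. WT mt− had 33 H3K9me1 peaks there, with a median distance of 1171 bp between the starts of neighbours less than 2 kb apart (quartiles 1099 and 1235 bp, 30 distances). H3K4me3 gave 29 peaks there in WT mt−, with a median distance of 1172 bp (1152 and 1225 bp, 25 distances). In WT mt+ there were 0 H3K9me1 peaks and 18 H3K4me3 peaks, the latter also spaced by a median of 1178 bp over 9 distances. In dnmt1 mt− the interval held 2 H3K9me1 and 18 H3K4me3 peaks, and in set3 mt− 30 H3K9me1 peaks with a median width of 343 bp, against 662 bp in WT mt−, and a wider spread of distances (median 1119 bp, quartiles 738 and 1303 bp, 24 distances). H3K9me3 peaks there numbered 0 in both WT strains.

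New H3K9me1 peaks of the mutants lay at H3K4me1 peaks more often than shifted lists did. Of the 1602 set3 mt+ peaks without a WT H3K9me1 peak, 241 (15.04%, 13.4 to 16.9) overlapped an H3K4me1 peak of WT mt+, against a chance median of 1.498%, and 902 (56.3%, 53.9 to 58.7) one of the longer dnmt1 mt+ list, against 10.6%. Of the 4552 in set3 mt−, 1036 (22.8%, 21.6 to 24.0) overlapped a WT mt− H3K4me1 peak, against 3.801%, and 276 (6.06%, 5.41 to 6.79) one of the shorter dnmt1 mt− list, against 0.769%. At H3K4me3 the shares were 0.187% and 0.505%, against chance medians of 17.0% and 17.8%. The dnmt1 lists behaved alike, with 14.3% (11.1 to 18.3) of 364 new peaks in mt+ and 25.6% (23.2 to 28.2) of 1161 in mt− at WT H3K4me1 peaks, against 1.65% and 3.36%. The labels give H3K4me1 and H3K9me1 separate input libraries.

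At 3 chromosome ends dnmt1 mt+ had over 5 kb more H3K9me1 than WT. The right end of chromosome 14 had 31.9 kb, where WT had 0 kb in both strains and dnmt1 mt− 0 kb. The right end of chromosome 8 had 17.5 kb, where WT had 0 kb in both strains and dnmt1 mt− 0.496 kb. The left end of chromosome 1 had 8.67 kb, against 2.85 kb in WT mt+ and 0.505 kb in dnmt1 mt−. Whether these ends hold repeated sequence, where copy number and read mapping affect peak calls, was not examined. No end was of this kind in dnmt1 mt− or in the set3 libraries. On contigs, the median local background at H3K9me1 summits, a scaled pileup, was 42.1 and 46.0 in WT, and 91.3 in dnmt1 mt+, 177 in dnmt1 mt−, 108 in set3 mt+ and 127 in set3 mt−, while in interiors it was 35 and 37.1 in WT and 20.5 to 39.0 in the mutants.

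On mating_type_plus the mt+ mutants had more H3K9me1 from 250 to 300 kb than WT mt+. The bin was covered to 2.15% in WT mt+, 7.18% in dnmt1 mt+ and 15.5% in set3 mt+, while the bin from 50 to 100 kb was covered to 2.19% in WT mt+ and to 0% in both mutants.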
